A study of Mus musculus with 12 samples.

How the data were processed

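Cut & Run libraries were made from mouse embryonic fibroblasts, which are connective tissue cells cultured from embryos, either wild type (WT) or knocked out for Fbxw7 (KO). In Cut & Run an antibody directs a nuclease to a chromatin protein or histone mark, and the DNA fragments it releases are sequenced. The antibodies were against MLL4 (the product of Kmt2d), H3K4me1 and H3K4me3. Each of the 3 antibodies was used in 2 libraries per genotype, giving 6 groups and 12 libraries. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical.

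Per the submitters' processing notes, the genome build was mm10 and the tools named were Bowtie2, SAMtools 1.5, bedtools, MACS2, deepTools and HOMER 4.10, with no role given. Per the file headers, the authors called peaks for each library on its own with MACS2 version 2.1.0.20150731 in paired-end mode. The headers give a q cutoff of 0.01, an extension size of 147, automatic duplicate handling, a local background over 10000 bp, narrow peaks and no control library. Per the file headers, duplicates were limited to 1 fragment per position in the MLL4 lists and in 3 of the 4 H3K4me3 lists, and to 2 in the H3K4me1 lists and in the H3K4me3 list of WT replicate 1. Each deposited list gives the peak's position, its pileup signal (the number of fragments over the summit, not scaled to depth), −log10 p and q values and a fold enrichment ratio over the local background. These −log10 values, the pileup signal and the fold ratio are the authors' own values for a peak within its library. They were used to describe, rank or filter peaks within a list and, for the pileup, to compare chromosomes within a library. The share of a list past a −log10 q cutoff was also compared between libraries, without adjustment for depth, on which q values depend. The same q cutoff keeps weaker sites in a deeper or more enriched library, so a missing peak means that a site did not pass in that library, not that the mark was absent.

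Depth was read from the file headers as fragments after duplicate filtering. The MLL4 libraries held 5629819 and 5838305 (WT) and 5743404 and 4435103 (KO). The H3K4me1 libraries held 12607690 and 11604131 (WT) and 13627038 and 12611409 (KO). The H3K4me3 libraries held 11319701 and 6185767 (WT) and 5519477 and 5938102 (KO). Shares of MLL4 peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Shares of histone peaks are given as the mean and SD of the 2 libraries.

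Peaks on chromosomes 1 to 19 and X were used. The 4 lists of a mark were merged into regions wherever peaks shared at least 1 bp, and a library held a region when it had a peak there. A region or gene is called WT-only when both WT libraries and neither KO library had a peak, and KO-only in the reverse case. The same counts were made for the other 2 ways of splitting the 4 libraries into pairs. Agreement between libraries was measured as the Jaccard index, the shared over the total bases covered. Gene positions came from a RefSeq table of GRCm38.p6, which has the coordinates of mm10. It lists start and end but neither strand nor exons, so the 5′ end could not be told from the 3′ end and exons could not be told from introns. A gene (21883 protein-coding) was therefore scored on a window of 1 kb either side of both of its ends, called gene ends here, where the plan had been transcription start sites. Because KO H3K4me3 peaks were shorter, genes were also scored with a window of 2 kb and over the whole gene plus 1 kb beyond its ends. Genes WT-only or KO-only in all 3 scorings are said to hold in all 3 windows.

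Differences between genotypes in values per library were tested with exact two-sided permutation tests over the 6 assignments of 4 libraries, whose smallest possible p is 0.333. No such comparison can pass 0.05, so none is described as a rise or a fall. The 15 gene lists were fixed before the data were examined: fibroblast, Fbxw7 substrates, Notch pathway, sterol synthesis, H3K4 methylation machinery, adipogenic, myogenic, cell cycle, housekeeping, Hox genes, pluripotency, haematopoietic, endothelial, epithelial and neural. Each was compared with all other genes holding a peak of the mark in at least 1 library, by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 60 tests. Changes of H3K4me1 over a fixed set of genes were tested with McNemar's exact test (two-sided). These tests count genes, not replicates, and describe these libraries. MLL4 peaks were compared with 100 random placements of the same lengths on the same chromosomes.

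Named regions followed a rule fixed at the same time as the lists. Fbxw7 came first. For each mark and direction, the 10 regions with the best rank followed, ranked by the lower of their 2 percentiles in the libraries that hold them, and named by a gene end within 1 kb for H3K4me3, or by the overlapped or nearest gene within 100 kb otherwise. For MLL4 up to 20 regions held by all 4 libraries were ranked in that way too. Members of the lists that were WT-only or KO-only were then named, with examples, in list order, held by all libraries or none. Some list members are not reported here by name, though the counts include them.

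Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The region step was tested on simulated data: 4 lists were made from the 17460 H3K4me3 peaks of WT replicate 1, peak ends were shifted by less than 30 bp, each peak was dropped from a list with a 5% chance, and 200 regions were removed from both simulated KO lists. Of these, 173 (86.5%) were recovered as WT-only, while 31 other regions were called WT-only and 45 KO-only by chance dropout. Real replicates disagreed more: 83.2% of the H3K4me3 peaks of KO replicate 1 overlapped replicate 2, and 75.9% the other way. The simulated dropout also ignored peak strength. The simulation thus checks the region step and does not estimate chance calls in the real lists. For the list test, 1000 random lists of 25 genes among the 11993 with an H3K4me3 peak gave a p under the threshold in 2.70% of cases. Lists simulated with 50% of members WT-only against a background of 16.7% gave such a p in 93.6%. Both rates count p-values without the adjustment that the real lists had to pass. Most real lists also had fewer than 25 members with a peak. The 93.6% is therefore not the power of the adjusted test on the real lists, which was not simulated.

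Alternatives were a stricter cutoff (−log10 q of at least 10), lists of equal length, other chromosome sets, other merging and overlap rules, other windows, the replicate number as a block, and leaving out each library. The analysis of chromosome 10, its omission, scoring over the whole gene and the overlap of MLL4 with histone peaks outside regions held by all 4 MLL4 libraries were added after the data had been seen. Peaks on the mitochondrial genome and the Y chromosome were left out of the comparisons.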

Results

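MLL4, H3K4me1 and H3K4me3 were profiled by Cut & Run in WT and Fbxw7 KO mouse embryonic fibroblasts, with 2 libraries per antibody and genotype. Fbxw7 is the substrate-recognition subunit of an SCF ubiquitin ligase. MLL4, encoded by Kmt2d, is a histone methyltransferase that deposits H3K4me1, a mark common at enhancers, while H3K4me3 marks active promoters. The comparisons ask whether the genomic distribution of each differs with loss of Fbxw7. Across the 12 libraries the depth was 4435103 to 13627038 filtered fragments. The deepest H3K4me3 library, WT replicate 1, held 11319701 against 5519477 to 6185767 in the other 3.

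The Fbxw7 gene itself (mm10, chromosome 3, 84814990 to 84979198) carried 11 and 10 H3K4me1 peaks in the WT libraries and 8 and 6 in the KO libraries. H3K4me3 peaks over the gene numbered 2 and 3 in WT and 1 and 1 in KO, and no library had an MLL4 peak there. The labels do not say which part of the gene was deleted, so these counts do not check the genotype labels. Kmt2d (chromosome 15, 98831669 to 98874077) carried 3 H3K4me3 peaks in each of the 4 libraries and 1 H3K4me1 peak in each of the 4.

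H3K4me3 peaks were fewer and shorter in both KO libraries than in either WT library, and a smaller share reached a high −log10 q. The KO lists held 10397 and 11281 peaks against 17460 and 16078 in WT, means of 10839 ± 625 and 16769 ± 977 (SD, n = 2 each; log2 KO/WT −0.63). The peaks covered 6.75 ± 0.710 Mb in KO and 19.8 ± 3.11 Mb in WT (SD, n = 2), and their median length was 559.5 ± 27.6 bp against 1136 ± 116 bp. By the authors' q values, 17.4 ± 4.16% of KO peaks and 78.3 ± 5.95% of WT peaks reached a −log10 q of 10, a share not adjusted for depth (74.1% in WT replicate 2 and 20.3% in KO replicate 2, of similar depth). The exact permutation p was 0.333 for each of these measures, the smallest that 2 against 2 libraries allow. KO replicate 2 had 0.960 times the fragments of WT replicate 2 and 0.702 times its peaks, whereas WT replicate 1 had 1.83 times the fragments of WT replicate 2 and 1.09 times its peaks.

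**Figure D1:**
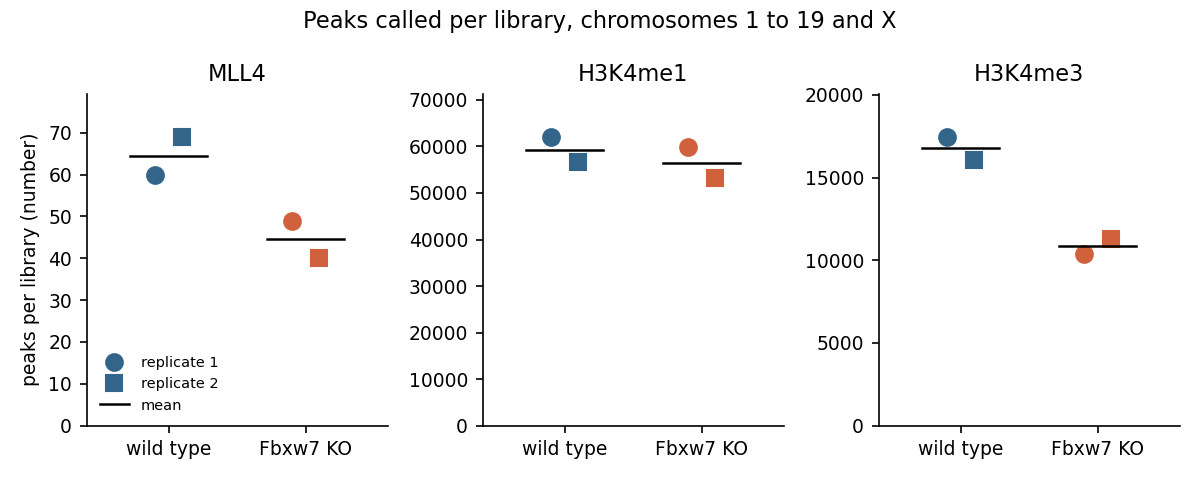
Number of peaks per library (vertical axis, from 0) for MLL4, H3K4me1 and H3K4me3 on chromosomes 1 to 19 and X, with circles for replicate 1, squares for replicate 2 and a line at the mean of the 2 libraries. The H3K4me3 lists hold 10397 and 11281 peaks in KO and 17460 and 16078 in WT, while the H3K4me1 genotypes overlap.

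Of 17842 merged H3K4me3 regions, 8345 had a peak in all 4 libraries, 3874 were WT-only and 10 were KO-only. The other 2 splits of the same libraries gave 19 and 5 regions, and 45 and 5. Without WT replicate 2 the WT-only regions numbered 6568, and without WT replicate 1, KO replicate 1 or KO replicate 2 the KO-only regions numbered 31, 61 and 42, since presence or absence in the reduced genotype then rests on 1 library. WT-only regions were mostly weak in WT, with a median percentile of 15.5 by rank in WT replicate 2, among regions held by both WT libraries, against 69.2 for regions in all 4 libraries.

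Among protein-coding genes, 11993 had H3K4me3 at a gene end in at least 1 library, 7564 in all 4, 1837 only in both WT libraries and 0 only in both KO libraries. Without KO replicate 2 the WT-only genes numbered 3088, and without WT replicate 1, KO replicate 1 or KO replicate 2 the KO-only genes numbered 5, 7 and 3. The WT-only status held in all 3 windows for 1256 of the 1837 genes; the others had a KO peak further from the gene end. The best-ranked WT-only regions at gene ends lay at Melk, a mitotic kinase gene (chromosome 4, 44300817 to 44301958, −log10 q 85.2 and 37.4 in the WT libraries), and at Rasl12, which encodes a Ras-like GTPase (chromosome 9, 65398442 to 65399539, 77.0 and 37.5). Ifit1bl1, Arhgap33, Hcrt, which encodes the neuropeptide hypocretin, and Pold4, a DNA polymerase delta subunit gene, followed. The remaining 4 of the 10 best-ranked regions, on chromosomes 4, 8, 11 and 16, had no gene end within 1 kb. Of the 10 KO-only regions, only 1 lay at a gene end, that of Sfi1 (chromosome 11, 3131907 to 3132345), a gene whose end carried another peak in WT.

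**Figure D2:**
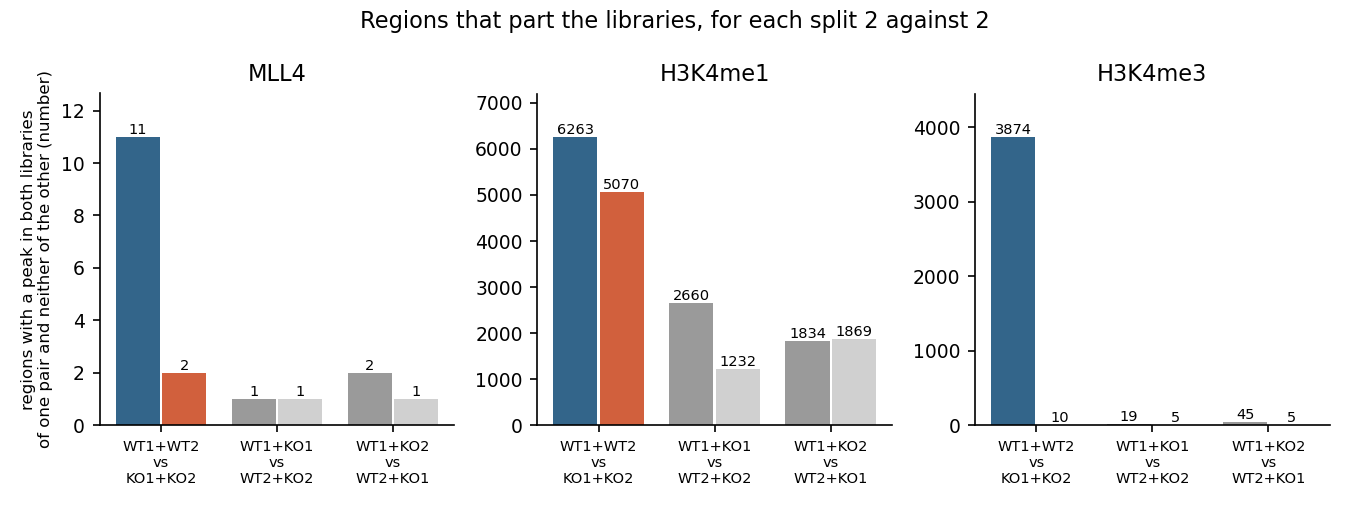
Number of merged regions (vertical axes, different scales) with a peak in both libraries of 1 pair and in neither of the other, for the 3 ways of splitting 4 libraries into pairs; blue bars are WT-only, orange bars KO-only and grey bars the other 2 splits. For H3K4me3 the genotype split gives 3874 WT-only and 10 KO-only regions, and for H3K4me1 6263 and 5070.

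The number of WT-only H3K4me3 regions depended on the peak threshold. With the 10397 best peaks of each list, 562 regions were WT-only and 193 KO-only (129 and 71, and 141 and 108, in the other splits), with 600 and 98 genes; at a −log10 q of at least 10, there were 8496 and 2 regions and 7148 WT-only genes. Requiring peaks over 50% of a region gave 8728 WT-only regions.

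Among the lists, Hox genes, which specify position along the body axis, had the highest share of WT-only H3K4me3 among those with at least 10 measured members. Of 28 with a peak, 11 (39.3%) were WT-only against 15.3% of other genes, and 6 had a peak in all 4 libraries, including Hoxa7 and Hoxb3. The WT-only members were Hoxa9, Hoxa11, Hoxb6, Hoxc4, Hoxc5, Hoxc6, Hoxc10, Hoxc13, Hoxd1, Hoxd8 and Hoxd11, of which Hoxc4, Hoxc5, Hoxc13, Hoxd1, Hoxd8 and Hoxd11 held in all 3 windows. The share did not pass correction (Fisher's exact p = 0.00181, adjusted p = 0.108), and with lists of equal length the excess over other genes was 9.26 percentage points against 24.0. Of the 26 Hox genes with H3K4me3 in both WT libraries 42.3% were WT-only, against a mean of 37.5% (central 95% 23.1 to 50%) in random lists matched on rank in WT replicate 2. Neural markers had a peak at only 3 of 14 members, and all 3, Tubb3, Map2 and Nes, which encode cytoskeletal proteins of neurons and neural progenitors, were WT-only in all 3 windows (Fisher's exact adjusted p = 0.108). This list passed with the 2 kb window (Fisher's exact adjusted p = 0.0182) and over the whole gene (0.0101), and with lists of equal length none of its members had a peak, so it gave no value.

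Cell cycle genes had H3K4me3 in at least 1 library at all 26 members; 14 had it in all 4 libraries, among them Ccnb1, Cdk1 and Cdk2, and 8 (30.8%) were WT-only (Fisher's exact p = 0.0489, adjusted p = 0.978). The WT-only members were the replication licensing genes Mcm2, Mcm3 and Cdc6, the mitotic genes Ccnb2 and Cdc20, and E2f2, all of which held in all 3 windows, and Ccna2 and Cdkn1a, which did not. In the Notch pathway, 4 of 14 members were WT-only and held in all 3 windows: the ligand gene Dll4, the target gene Hes1, and the modulators Dtx1 and Lfng. Notch2, Hes7 and Ccnd1 had H3K4me3 in all 4 libraries (Fisher's exact p = 0.252 for the list).

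Fibroblast genes showed both patterns. Of 27 members, 5 had no H3K4me3 peak at a gene end in any library. Of the 22 with a peak, 10 had H3K4me3 in all 4 libraries, including Col5a2, Col6a1, Col6a2 and Thy1. WT-only were 4: Col1a2, Col5a1, Lum and Twist2, the last 2 in all 3 windows. The other 8 had mixed patterns. Fbxw7 substrates were WT-only at 3 of 20, Junb in all 3 windows, Notch4 and Hif1a in the 1 kb window, while Ccne2, Notch1, Srebf2 and Klf5 had a peak in all 4 libraries. Sterol synthesis genes had H3K4me3 in all 4 libraries at 18 of 21, including Hmgcs1 and Sqle, and 1, Fasn, was WT-only in the 1 kb window. The H3K4 methylation machinery had it in all 4 libraries at 12 of 18, including Kmt2b, Kmt2c and Kmt2d, with Setd1b, Kdm6a and Kdm5b WT-only in the 1 kb window. Housekeeping genes were WT-only at 4 of 17, among them Gapdh and Tbp in the 1 kb window and Eef1a1 in all 3 windows, and in all 4 libraries at 7, including Ppia and Rps18. Adipogenic genes had all 4 libraries at 6 of 11, including Pparg and Cebpa, and Ebf2 was WT-only in all 3 windows. The share of WT-only genes was 18.2% for fibroblast, 15.0% for substrate, 16.7% for machinery and 23.5% for housekeeping genes. It was 4.76% for sterol synthesis and 9.09% for adipogenic genes, against 15.3% of other genes. The smallest unadjusted Fisher's exact p among these lists was 0.235 (sterol synthesis), so the named WT-only genes do not set their lists apart.

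Markers of other lineages were mostly without H3K4me3. Pluripotency genes had a peak at 1 of 13 (Tfcp2l1, WT-only), haematopoietic genes at 2 of 15 (Spi1 WT-only), myogenic genes at 2 of 15 (Pax3 WT-only), endothelial genes at 2 of 12, with Flt1 in all 4 libraries, and epithelial genes at 1 of 13, so most of the named markers of these cell types, such as Pou5f1, Ptprc, Myod1, Pecam1 and Cdh1, had none. Of 60 list tests over H3K4me3 and H3K4me1, 0 passed at an adjusted p of 0.05 by Fisher's exact test. Of these, 3 had an unadjusted p under 0.05, those of the Hox, neural and cell cycle lists for WT-only H3K4me3. The KO-only H3K4me3 tests could not pass, as no gene was KO-only. Neither could the H3K4me1 tests of the pluripotency list, which had no member with a peak. These empty tests still counted among the 60 in the adjustment. Very short lists could not pass either. For WT-only H3K4me3, the single pluripotency gene with a peak was WT-only, yet its Fisher's exact p was 0.153. The neural list had all 3 measured members WT-only and still had an adjusted p of 0.108. The count of 0 passing tests is therefore partly set by list size.

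**Figure D3:**
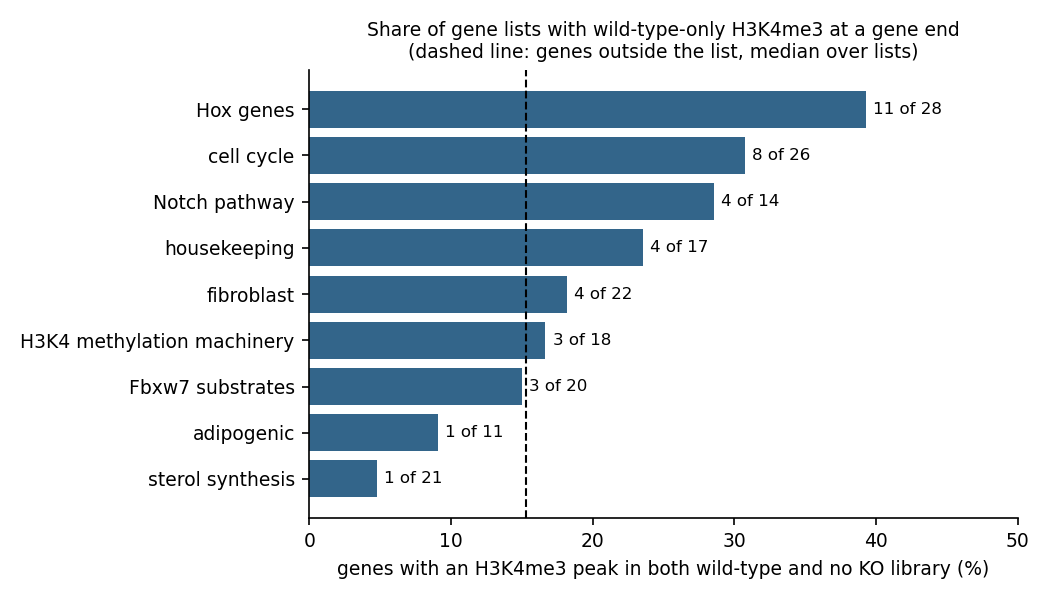
Share of the genes of each list with H3K4me3 at a gene end in both WT libraries and neither KO library (horizontal axis, %), among members with a peak in at least 1 library, for lists with at least 10 such members; the dashed line is the share among genes outside the list. Hox genes stand at 39.3% (11 of 28) and sterol synthesis genes at 4.76% (1 of 21), against 15.3%.

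H3K4me1 peak numbers differed between genotypes by less than the spread between replicates, and part of the regions were called in 1 genotype only. The lists held 62065 and 56616 peaks in WT and 59908 and 53120 in KO, means of 59340.5 ± 3853 and 56514 ± 4800 (SD, n = 2 each; log2 KO/WT −0.07, exact permutation p = 0.667). The sign of this difference turned without KO replicate 2 (log2 0.015). Of 94400 merged regions, 27093 had a peak in all 4 libraries, 6263 were WT-only and 5070 were KO-only, against 2660 and 1232, and 1834 and 1869, in the other splits. Another 34555 regions had a peak in 1 library only. The Jaccard index was 0.431 within WT, 0.412 within KO and 0.349 to 0.373 between genotypes. At equal list length the counts were 5488 and 5318 (1797 and 1665, and 1785 and 1718, in the other splits). At the stricter cutoff they were 1264 and 668 (848 and 284, and 428 and 509, in the other splits). Without WT replicate 1, WT replicate 2 or KO replicate 1 there were 14761, 17394 and 11244 WT-only regions, and without WT replicate 1, KO replicate 1 or KO replicate 2 there were 8859, 12199 and 15468 KO-only regions, since presence or absence in the reduced genotype then rests on 1 library.

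The 10 best-ranked WT-only H3K4me1 regions included sites inside Inpp5a, an inositol polyphosphate phosphatase gene (chromosome 7, 139549723 to 139550925, −log10 q 15.9 and 14.5), Fam53c (chromosome 18, 34769036 to 34769620, 14.2 and 16.0), Ulk4, Cachd1, Gad2, Raver2 and Plekha6. A site at a gene end of Pnkd and sites near Clint1 and Pdia6 completed the 10. Best-ranked KO-only regions lay near Pcdh15, a protocadherin gene (chromosome 10, 73068048 to 73069990, 14.4 and 15.3), Fut10, Icosl, Gm28710, Ptprr and Slc38a10, and inside Plxnc1, a semaphorin receptor gene; 3 had no gene within 100 kb. Those of Pcdh15, Icosl, Ptprr and Plxnc1 were all on chromosome 10. That chromosome held 588 of the 5070 KO-only regions (11.6%) and 259 of the 6263 WT-only regions (4.14%). Its share of a library's H3K4me1 peaks was 7.44 ± 0.150% in KO and 5.95 ± 0.0123% in WT (SD, n = 2, exact permutation p = 0.333). The mean summit pileup on chromosome 10 was 1.16 to 1.24 times that on the other autosomes in the 4 KO histone libraries and 0.981 to 1.01 times in the 4 WT ones. Without chromosome 10 there were 6004 WT-only and 4482 KO-only regions. Other chromosomes differed less: the KO over WT share of H3K4me1 peaks was 1.16 on chromosome 16, 0.904 on 4 and 0.903 on 19. Relative mean pileup, KO over WT, went the same way there (1.05, 0.944 and 0.951 for H3K4me1). The remaining counts are therefore not cleared of differences along whole chromosomes.

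**Figure D4:**
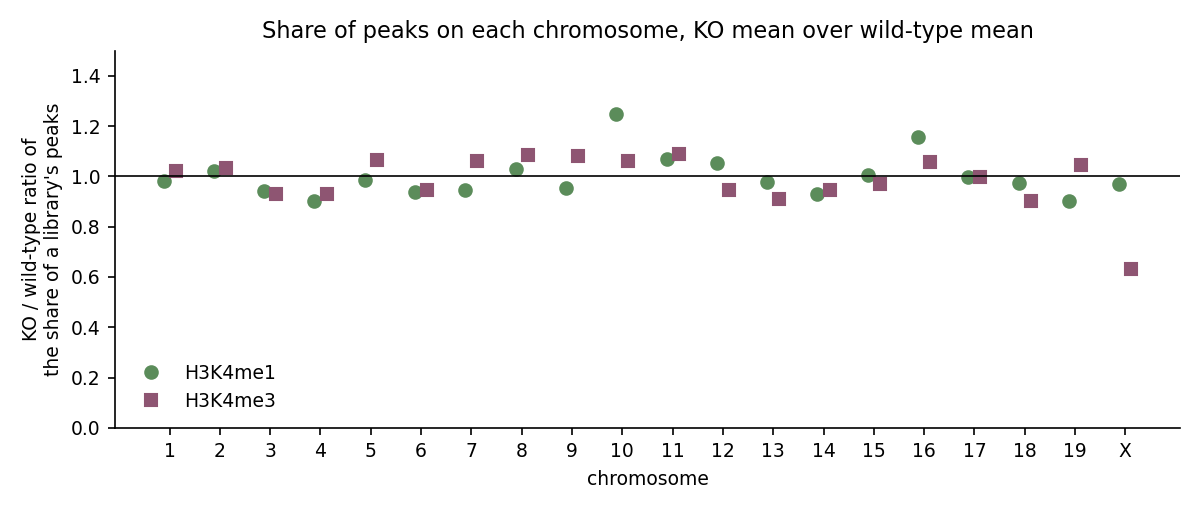
Ratio of the mean KO share to the mean WT share of a library's peaks (vertical axis) for each chromosome (horizontal axis), with circles for H3K4me1 and squares for H3K4me3. Chromosome 10 has the highest H3K4me1 ratio (1.25) and X the lowest H3K4me3 ratio (0.633).

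At gene ends, H3K4me1 was WT-only at 383 genes and KO-only at 315, of 6069 with a peak. The other splits, which do not separate the genotypes, gave 282 and 123, and 198 and 206. The call of a single gene named below therefore need not follow genotype. Of the WT-only and KO-only genes, 165 and 113 held in all 3 windows. Fibroblast genes had H3K4me1 in all 4 libraries at 11 of 19 members, including the collagen genes Col1a2, Col5a1, Col5a2 and Col6a1, with Sparc KO-only in all 3 windows. The transcription factor gene Cebpa, on the adipogenic and the substrate lists, was KO-only in all 3 windows, and Cebpd was KO-only in the 1 kb window. In the sterol list Insig1, an inhibitor of SREBP processing, and Scd1, a fatty acid desaturase, were WT-only in all 3 windows, and Scd2 had a peak in all 4 libraries. The adipokine gene Retn and the endothelial cadherin gene Cdh5 were WT-only in all 3 windows, and Mcm5 and Hoxd4 were KO-only in all 3. In the 1 kb window, but not in all 3, E2f1 and Hoxd3 were KO-only and Mcm6, Hoxc5, Chrna1 and Cx3cr1 were WT-only. None of the 13 pluripotency genes, such as Pou5f1, Nanog and Sox2, had H3K4me1 at a gene end in any library, while scoring over the whole gene found 2 with a peak. In the Notch, methylation machinery, housekeeping, epithelial and neural lists no member was WT-only or KO-only for H3K4me1 in the 1 kb window. The stricter cutoff left 53 WT-only and 28 KO-only genes, a 2 kb window gave 655 WT-only genes and the whole gene 600, and a 500 bp window gave 198 KO-only genes. Without WT replicate 1, WT replicate 2 or KO replicate 1 the WT-only genes numbered 873, 1134 and 720, and without WT replicate 1, KO replicate 1 or KO replicate 2 the KO-only genes numbered 574, 817 and 1096.

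At the genes that were WT-only for H3K4me3, the share with H3K4me1 did not pass a test between genotypes. Of these 1837 genes, 13.6% had H3K4me1 at a gene end in both WT libraries and 12.6% in both KO libraries (McNemar's exact p = 0.217). Per library the shares were 23.9% and 18.5% in WT and 24.4% and 18.9% in KO. Among the 7564 genes with H3K4me3 in all 4 libraries the shares were 11.2% and 10.3% (McNemar's exact p = 0.0184). Among the 9890 with no H3K4me3 peak they were 5.80% and 4.95% (McNemar's exact p = 1.64e-05). The KO minus WT difference was similar in these classes, at −0.980, −0.886 and −0.849 points in the order given. The classes differ in gene number, so their p-values do not show that H3K4me1 behaved differently at WT-only genes. For the WT-only genes, a 2 kb window gave a difference of −3.26 percentage points (McNemar's exact p = 0.00168), and the sign turned at equal list length (1.00 percentage point). It also turned without KO replicate 1 or 2 (5.76 and 11.2 points) and stood at −5.73 and −10.7 points without WT replicate 1 or 2, as a genotype with 1 library needs 1 peak.

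MLL4 gave few peaks, and those at gene ends were almost all in WT libraries. The lists held 60 and 69 peaks in WT and 49 and 40 in KO, means of 64.5 ± 6.36 and 44.5 ± 6.36 (SD, n = 2 each; log2 KO/WT −0.54, exact permutation p = 0.333). At gene ends lay 10 of 60 (16.7%, 95% interval 8.29 to 28.5) and 12 of 69 (17.4%, 9.32 to 28.4) WT peaks, against 1 of 49 (2.04%, 0.0517 to 10.9) and 0 of 40 (interval up to 8.81%) KO peaks, means of 17.0 ± 0.512% and 1.02 ± 1.44% (SD, n = 2, exact permutation p = 0.333). The genes with MLL4 in both WT libraries and neither KO library were Ell, a transcription elongation factor gene (chromosome 8, peak 70539014 to 70539262), Zfpm1, which encodes a GATA cofactor (chromosome 8, 122281564 to 122281891), Fkbp2 and the overlapping LOC114841036 (chromosome 19, 6980207 to 6980465), and the neighbours Usp5 and Cdca3, which share a peak (chromosome 6, 124829173 to 124829441). Lars2 had MLL4 in both WT libraries and KO replicate 1. The immediate-early gene Egr1, the NuRD complex gene Mbd3, Cic, Ensa, Sec16a, Sfi1 and Tubb4b had it in WT replicate 2 alone, and the kinase gene Gsk3b, Sp4, Rras, Fbxo5, Dazap1 and Gamt in WT replicate 1 alone. All 20 genes had H3K4me3 in both WT libraries, and 17 had it in both KO libraries. No control library was used and these sites were not screened, so the peaks are not shown to be specific MLL4 binding.

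Of 93 merged MLL4 regions, 23 were held by all 4 libraries, 11 were WT-only and 2 KO-only, against 1 and 1, and 2 and 1, in the other splits. With the 40 best peaks of each list the counts were 7 and 7, and at the stricter cutoff 4 and 1, while merging peaks within 1000 bp gave 1 KO-only region. Without WT replicate 1, WT replicate 2 or KO replicate 1 there were 26, 21 and 19 WT-only regions, and without WT replicate 2 or KO replicate 2 there were 7 and 10 KO-only regions. The best-ranked WT-only region lay inside Aida (chromosome 1, 183299162 to 183299424, −log10 q 38.6 and 52.2), and another inside Sfi1. One of the 2 KO-only regions lay 79941 bp from Rpia and the other had no gene within 100 kb. The latter, on chromosome 14 (19415736 to 19416002), lay near the top-ranked region held by all 4 libraries (19416915 to 19417350). On chromosome 17, WT-only regions at 39846290 to 39846749 and 39848267 to 39848678 lay near another such region (39843366 to 39845963). These neighbours of shared regions were not screened either, so they need not be separate MLL4 sites. None of the 23 regions held by all libraries was at a gene end; 17 overlapped an H3K4me3 peak in all 4 libraries of that mark, and 12 overlapped a peak in all 8 histone libraries. No list of high-signal regions was used here, so regions that any antibody would recover were not screened out. The top-ranked of them were on chromosome 14 (19416915 to 19417350), chromosome 2 (98666322 to 98667306) and chromosome 9 (3020225 to 3020549 and 3000366 to 3001035), with no gene within 100 kb, followed by sites inside Slc22a22, Zc3h7a, Atp8b5, Frem3, Usp24 and Csmd1.

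MLL4 peaks lay on H3K4me1 peaks common to both libraries of the genotype in 20.3 ± 2.00% of cases in WT and 47.4 ± 3.61% in KO (SD, n = 2, exact permutation p = 0.333). For H3K4me3 the shares were 47.4 ± 1.38% and 66.6 ± 4.76% (exact permutation p = 0.333), a difference of 19.3 percentage points that stood at 5.76 without WT replicate 1, 6.63 without WT replicate 2 and 35.1 without KO replicate 1. Random placements gave means of 1.48 to 2.29% on H3K4me1 and 0.425 to 1.09% on H3K4me3. The KO overlaps were 22 of 49 and 20 of 40 peaks on H3K4me1 and the WT overlaps 13 of 60 and 13 of 69. Many of these lay in the unscreened regions held by all 4 MLL4 libraries, 18 in each KO library and 12 in each WT library. Without those regions, the shares on H3K4me1 were 2.44 ± 0.374% in WT (1 of 37 and 1 of 46) and 14.3 ± 2.47% in KO (4 of 25 and 2 of 16), and on H3K4me3 32.5 ± 0.125% and 41.9 ± 2.65% (SD, n = 2, exact permutation p = 0.333 each).

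**Figure D5:**
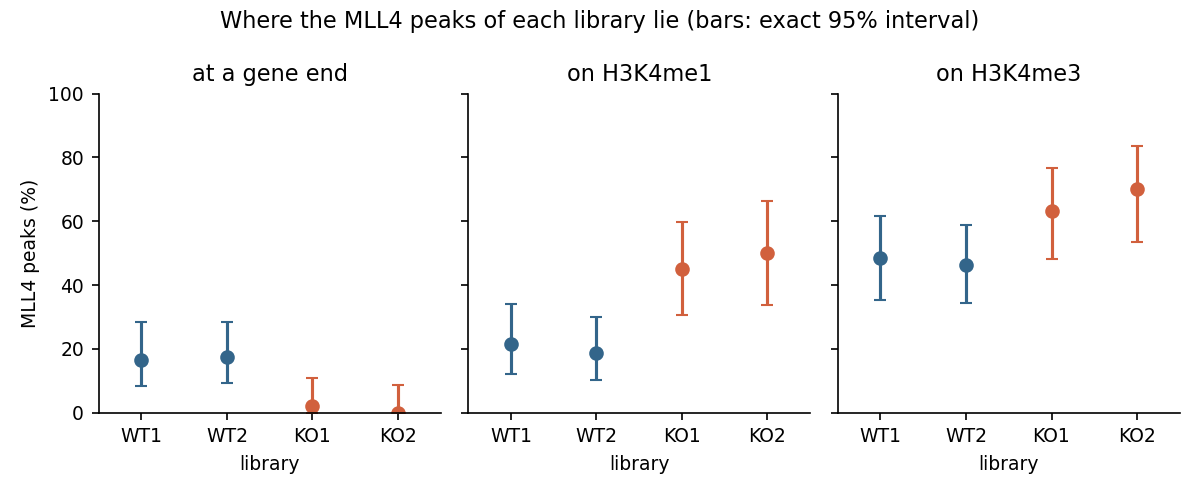
Share of the MLL4 peaks of each library (vertical axis, %) that lie at a gene end, on an H3K4me1 peak or on an H3K4me3 peak held by both libraries of the same genotype; points are libraries and bars exact 95% intervals. Gene-end shares are 16.7 and 17.4% in WT and 2.04 and 0% in KO.

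By location, 75.7 ± 0.248% of KO and 67.7 ± 2.99% of WT H3K4me3 peaks were at gene ends (SD, n = 2, exact permutation p = 0.333). H3K4me1 peaks were at gene ends in 5.46 ± 0.331% (KO) and 5.37 ± 0.282% (WT) of cases, with an exact permutation p of 0.667. The Jaccard index of H3K4me3 was 0.750 within WT, 0.485 within KO and 0.281 to 0.396 between genotypes. For MLL4 it was 0.593, 0.527 and 0.444 to 0.480.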

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

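The tests of depth, enrichment, antibody recovery and chromosome 10 were chosen after the result had been seen, as were the groups compared with lists matched on WT rank, whose matched test was fixed before its outcome was seen. Signal appeared in 2 places outside the comparisons. Peaks on the mitochondrial genome were called in all 12 libraries, on average 4.75 for MLL4 (3 to 6), 5.25 for H3K4me1 (4 to 7) and 4.75 for H3K4me3 (4 to 5). H3K4me3 peaks on the Y chromosome numbered 4.25 on average (3 to 5). No control library was used for either.

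Both KO libraries had fewer H3K4me3 peaks than either WT library. Lower sequencing depth is argued against by KO replicate 2, which had 0.702 times the peaks of WT replicate 2 at 0.960 times its fragments. Weaker enrichment spread over all regions may account for most of the pattern: the WT-only regions had a median percentile of 15.5 in WT replicate 2, against 69.2 for regions in all 4 libraries, and of regions in both WT libraries, 75.8% of the lowest-ranked 25% but 0.845% of the highest-ranked 25% were missing from both KO libraries. At equal list length 562 regions were still WT-only, more than the 129 and 141 of the other splits. This does not decide whether a weakening alike at all regions is enough, as lists of equal peak number need not hold equal region numbers. In the full lists, 10397 and 11281 KO peaks fell in 9344 and 10015 regions. The 17460 and 16078 WT peaks fell in 17383 and 15033. The other splits pair a WT with a KO library, so such an imbalance would be less visible there. Whether the weaker signal came from lower antibody recovery in these libraries or from a lower level of the mark after Fbxw7 loss cannot be told apart, since no spike-in value was used here; the H3K4me1 peak number (KO over WT 0.952) does not bear on the recovery of another antibody.

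KO libraries had a higher share of H3K4me1 peaks on chromosome 10. Changes at a few loci are argued against, because without the 3 of 13 bins of 10 Mb with the largest excess the KO-only regions still outnumbered the WT-only ones 2.07 times. KO-only exceeded WT-only in all 13 bins, though only by 41 to 40 in the bin from 80 Mb. Extra copies of chromosome 10 in the KO cells are a candidate explanation: mean pileup on chromosome 10 was 1.16 to 1.24 times that on other autosomes in the 4 KO histone libraries and 0.981 to 1.01 times in the 4 WT ones. Copy number was not measured here, and an effect of the genotype spread along the whole chromosome stays open. The smaller differences in share on chromosomes 16, 4 and 19 were not tested. KO-only H3K4me1 regions on that chromosome, those of Pcdh15, Icosl, Ptprr and Plxnc1 included, may follow from it.

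WT-only H3K4me3 was uneven between groups of genes, and weak WT peaks may account for this. Against 10000 random lists matched on rank in WT replicate 2, among genes with H3K4me3 in both WT libraries, 42.3% of 26 Hox genes were WT-only (central 95% of matched lists 23.1 to 50%). WT-only status was also found at 61.5% of 26 homeobox and T-box genes outside Hox (34.6 to 65.4%) and 62.5% of 16 Wnt and Fgf genes (31.3 to 75%), against 16.2% of all such genes. On chromosome X, 40.7% of 477 regions were WT-only against 26.4% of all, below the matched range of 41.1 to 48.0%, so weak peaks alone would give a share at least as large, and the test, set to look for a share above the range, decides nothing there. No excess beyond peak strength was detected in the other 3 groups (one-sided permutation p 0.340, 0.131 and 0.325), which does not exclude a smaller one.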

How the results depend on the processing

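Of the alternatives, omission of chromosome 10, scoring over the whole gene, omission of the regions held by all 4 MLL4 libraries and those for the chromosome 10 share were chosen after the data had been seen. Of 167 alternative values, 110 kept their direction and side of the threshold or stayed within 1.5 times the count, and 48 counts moved further. Without reversing, 5 passed a threshold not passed before. The other 4 reversed, and were counted as reversed whether or not they also passed a threshold. Tests of 2 against 2 libraries cannot pass, so their stability shows nothing. H3K4me3 peak number (log2 −0.63) ranged from −2.82 (stricter cutoff) to −0.57. H3K4me1 peak number (log2 −0.07) was −0.37 at the stricter cutoff and −0.16 to 0.015 when a library was left out, reversed without KO replicate 2 (the cause was not tested). At the stricter cutoff the WT-only and KO-only regions numbered 4 and 1 (MLL4), 1264 and 668 (H3K4me1) and 8496 and 2 (H3K4me3), with 7148 WT-only H3K4me3 genes and 53 WT-only and 28 KO-only H3K4me1 genes; H3K4me3 went up because few KO peaks reach the cutoff (17.4 ± 4.16%). At equal list length they were 7 and 7 (MLL4) and 562 and 193 (H3K4me3), with 600 and 98 H3K4me3 genes. Requiring peaks to cover 50% of a region gave 8728 WT-only H3K4me3 regions. KO H3K4me3 peaks were shorter (median 559.5 against 1136 bp), but whether this is the cause was not tested. Merging within 1000 bp gave 1 KO-only MLL4 region. The other, on chromosome 14 (19415736 to 19416002), then joined the region held by all 4 libraries that starts at 19416915. A 500 bp window gave 1 KO-only H3K4me3 gene and 198 KO-only H3K4me1 genes, a 2 kb window 655 WT-only H3K4me1 genes and the whole gene 600, as windows of other sizes reach other peaks. In the list test 1 list (neural) passed with 2 kb and 1 over the whole gene; at equal list length no neural gene had H3K4me3, so it gave no value. Without regions held by all 4 MLL4 libraries, the KO minus WT share of MLL4 peaks was 11.8 points on H3K4me1 and 9.35 on H3K4me3. Leaving out 1 library relaxes the calls and raised most counts: WT-only and KO-only regions 16 to 26 and 2 to 10 (MLL4), 9243 to 17394 and 7532 to 15468 (H3K4me1), 4786 to 6568 and 15 to 61 (H3K4me3), genes 1886 to 3088 and 0 to 7 (H3K4me3), 571 to 1134 and 463 to 1096 (H3K4me1). H3K4me1 at WT-only H3K4me3 genes (−0.980 points) gave −3.26 with 2 kb, 1.00 at equal list length, reversed, and −10.7 to 11.2 without 1 library, reversed without either KO library; the cause was not tested except that 1 peak then suffices. With the replicate number as a block, log2 KO/WT stayed at −0.54 (MLL4), −0.07 (H3K4me1) and −0.63 (H3K4me3), smallest possible p 0.5, and no call changed. Same-numbered libraries did not deviate together over regions (correlations −0.0043, −0.0064 and 0.023), which does not exclude a shared batch. The H3K4me1 list of replicate 1 was the longer in both genotypes (62065 against 56616 in WT, 59908 against 53120 in KO). For MLL4 and H3K4me3 the replicate with the longer list differed between genotypes. Scoring the 5′ end alone was not run, as strand was not given in the gene table used here. MLL4 gave 40 to 69 peaks per library; whether depth limits this was not tested.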

Other observations

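The families below, defined by gene symbol, and the genes named for H3K4me1 regions were chosen after the results had been seen, and 52 family tests were made. Those for KO-only H3K4me3 could not pass, as no gene was KO-only. Of 30 homeobox and T-box genes outside Hox with a peak, 16 (53.3%) were WT-only against 15.2% of other genes (Fisher's exact adjusted p = 3.81e-05), with Lhx6, Irx5, Meis1 and Nkx3-2 among the 13 that held in all 3 windows, while Irx3, Tbx15 and Tbx18 had H3K4me3 in all 4 libraries. Of 19 Wnt and Fgf genes, 10 (52.6%) were WT-only (Fisher's exact adjusted p = 0.00176), among them Wnt4, Wnt11, Wnt2b, Fgf7 and Fgf18 in all 3 windows, while Fgf10 and Wnt9a had it in all 4 libraries. Protocadherins were WT-only at 15 of 30 (Fisher's exact adjusted p = 0.000154), for example Pcdh10, Pcdh19 and Pcdh20, and 9 of the 15 held in all 3 windows. Histone genes were WT-only at 18 of 57 (31.6%, Fisher's exact adjusted p = 0.0170), including H2ac4, H3c2 and H4c4, but many are near-identical copies, where short fragments are hard to place. With lists matched on WT rank the homeobox and Wnt and Fgf shares (61.5% and 62.5%) lay within the matched range; the protocadherin and histone shares were not matched in this way, so weak WT peaks were not tested as their cause.

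Mitochondrial ribosomal protein genes were WT-only at 2 of 74 and had H3K4me3 in all 4 libraries at 67 (Fisher's exact adjusted p = 0.00804). By the same test, respiratory complex I genes were WT-only at 1 of 46 (Fisher's exact adjusted p = 0.0405), ribosomal protein genes at 4 of 88 (0.0170), and Zfp zinc finger genes at 25 of 318 (7.86%, 0.000944). Proteasome genes (1 of 42, Fisher's exact adjusted p = 0.0830), collagens (6 of 22, 0.535), Sox and Fox factors (6 of 35) and solute carriers (27 of 208) did not pass. None of the families in this paragraph was matched on WT rank. For H3K4me1, 20 of 26 protocadherin genes counted as WT-only, but all 20 rest on 1 region at gene ends that the clustered genes share, so the count is not of independent genes.

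The genes named next were picked for an excess of KO-only or WT-only H3K4me1 regions. Ctnna3 (chromosome 10) held 17 KO-only and 1 WT-only regions, and Pcdh15 (chromosome 10) 18 and 5. Off that chromosome, Ptprd held 14 and 0, Pcdh9 8 and 1, and Cdh12 7 and 0. In the other direction, Cdk14 held 10 WT-only and 0 KO-only regions, Lrmda 10 and 2, Npas3 7 and 0, and Tcf7l2, a Wnt pathway transcription factor gene, 6 and 0. No test was made of single genes, or of clustering against gene length or the number of regions per gene.

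On the Y chromosome, Kdm5d, which encodes a histone demethylase, had an H3K4me3 peak in all 4 libraries. Uty and Ddx3y had one in both WT libraries and KO replicate 1, and Eif2s3y in both WT libraries. Each KO MLL4 library had 1 peak on the Y chromosome and neither WT library had one.

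The mean fragment size per the file headers was lower in KO for each antibody: 224 bp in both KO MLL4 libraries against 227.5 ± 0.707 bp in WT, 240.5 ± 0.707 against 248 ± 1.41 bp for H3K4me1, and 230.5 ± 0.707 against 240.5 ± 0.707 bp for H3K4me3 (SD, n = 2, exact permutation p = 0.333 each). The share of H3K4me3 peaks on H3K4me1 peaks of the same-numbered library of the genotype was 21.2 and 13.2% in WT and 5.80 and 4.82% in KO; the KO H3K4me3 peaks were shorter (median 559.5 against 1136 bp) and more often at gene ends, and the share was not compared with random placement or adjusted for length.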
